A study of Mus musculus with 136 samples.

How the data were processed

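The samples were single cells from the bone marrow of C57BL/6 mice. Per the labels' protocols, marrow was enriched for CD117 with magnetic beads and sorted by flow cytometry for granulocyte-monocyte progenitors (GMP), defined as lineage-negative, CD117-positive, Sca-1-negative, CD16/32-positive and CD34-positive cells. Cells were captured on a Fluidigm C1 microfluidic system, cDNA was made with a SMARTer kit and libraries with a Nextera XT kit. The sample titles divide the 136 cells into a set named R2 (68 cells) and a set named R3 (68 cells), and mark 4 R2 cells as being of poor quality. The labels do not say what R2 and R3 stand for, and they name no animal.

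The deposited values were log2(TPM + 1), where TPM is each transcript scaled to a fixed total per cell, in a table of 23955 gene symbols. The scale was read from the values: with the logarithm undone, each cell summed to the same total, in steps of 0.01 TPM. The design fixed beforehand had assumed linear values, so the deposited log2 values were first converted back to TPM. Per the submitters' processing notes, Bowtie2, RSEM and the mouse build mm9 were used. Their versions and the gene annotation are not given in the sources used here. TPM keeps no record of sequencing depth, so the depth of each cell is unknown and no floor was set for a value of 0. The table had 0 mitochondrial symbols, so a mitochondrial share was not computed. Of the deposited values, 77.7% were 0. How reads shared between near-identical genes were divided is not stated beyond the use of RSEM, so levels of multigene families (Ly6, Ear, Hba and Hbb, H2, Pyhin and Ms4a genes) are uncertain. No reference of build mm9 was used here and no coordinates are given.

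A gene was called detected in a cell above 1 TPM. The 4 cells of poor quality were described and then left out. R2 cells 54 and 56 had nearly the same values and were averaged and counted as 1 cell, which left 131 cells, 63 from R2 and 68 from R3. No other cell was removed. No doublet caller was run, because the cells were captured singly and there were no raw counts to run one on, so a capture site that held a pair of cells would remain. The groups, gene lists, rules, tests and alternatives described here were fixed before the data were examined, apart from the averaging of the pair of alike cells and the additions named in the closing section.

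Because no animal is named, each set counted as 1 sample. No p-value or standard error was made from cells and no gene was called changed between the sets. Counts of genes past a size of difference between the sets are descriptions. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error alone. Agreement between R2 and R3 served as the check on each relation.

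Of the named list genes, 3 were found under an older symbol: Wfdc21 as 1100001G20Rik, Adgre1 as Emr1 and Siglecf as Siglec5. Ly6g was not found in the table. A score was the mean of per-gene z values of log2(TPM + 1), standardised within each set, over list members detected in at least 5% of cells. The axis was the granulocytic score minus the monocytic score. Each gene detected in at least 10% of cells was related to the axis by Spearman's rho in each set, with a list member left out of its own score. A gene passed where rho was at least 0.4, or at most -0.4, with the same sign in both sets. The size of a relation is given as a slope, the change in log2(TPM + 1) per standard deviation of the axis, a scale that understates changes of low genes. The number of passing genes was set beside that from 200 axes made of random genes. Score correlations, list medians and gene pairs were set beside 10000 random lists or pairs of the same size, each member drawn from the 50 genes nearest in mean level. Members were drawn singly, so random lists need not vary together as the genes of a programme do. A list stood apart where its percentile was above 97.5 or below 2.5 in both sets. Lists with fewer than 3 members detected in 5% of cells got no median.

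The lists were primary granule, granulocytic, monocytic, dendritic, stem and multipotent, megakaryocytic, erythroid, basophil and mast cell, eosinophil, B lymphoid, T and NK, macrophage, and stroma and endothelium markers. Further lists held S phase, G2/M, immediate-early, heat shock, interferon response, p53 target, sort gate, sex-linked, transcription factor and ribosomal protein genes. Along the axis the text names the 12 genes at each end that were on no list, ranked by the smaller rho of the sets, and every passing member of the granulocytic, monocytic, primary granule and transcription factor lists. For detection it names the sort genes and up to 4 members per list, and between sets the 5 genes with the largest difference each way and the sex-linked genes. A gene named outside this rule is said to be chosen after its values were seen.

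Cells were clustered with the Leiden method at resolution 1 on a graph of 10 nearest neighbours in 10 principal components of the 1000 most variable genes, chosen within 20 bins of mean level after set means were removed. A cluster took a name where at least 3 of its top 10 genes by log2 difference were markers of that class, and more than of any other class. Sets were compared by mean log2(TPM + 1) per gene.

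The axis step was tested on simulated data built on the real genes and cells. Of 50 genes given a correlation of 0.4 with the simulated axis, 12% passed. The share was 86% at 0.6 and 100% at 0.8. Genes with a true correlation near the threshold were therefore mostly missed. Of 8864 unrelated genes, 0 passed. Their values had been shuffled gene by gene within each set, which removes their ties to other genes. This 0 is therefore no measure of false passes in the real cells. The simulated scores were opposed at a pooled rho of -0.873, against -0.447 in the real cells, so the simulated axis was cleaner and recovery in the real cells was not measured. The alternatives covered the pseudocount (0.1 in place of 1), Pearson correlation, adjustment for genes detected, the poor-quality cells, rescaling without ribosomal protein genes and the 50 most abundant genes, every measured list member, each set alone, thresholds and filters, and clustering settings. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.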

Results

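Transcript levels were measured in single granulocyte-monocyte progenitors, the marrow cells that give rise to granulocytes and monocytes. The series was made to study developmental hierarchies among blood-forming cells, and the comparisons below ask which lineage programmes were present in these cells and how they varied from cell to cell. There were 136 cells, of which 132 were not marked as poor in quality. Cells of the R2 set (n = 64) had a median of 4480 detected genes (quartiles 3872 and 4918) and R3 cells (n = 68) a median of 4912 (quartiles 4459 and 5243). The 4 cells marked as poor in quality had 601, 760, 794 and 953 detected genes, below the lowest of the other cells (2432). In these 4 cells the 50 most abundant genes held 48.5% to 98.2% of the transcripts, against a median of 26.3% in the others. Sequencing depth is unknown, so a gene that was not detected is not shown to be absent. R2 cells 54 and 56 correlated at r = 0.996 across genes, against 0.751 for the next closest pair of the table. They were counted as 1 sample, leaving 131 cells.

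Transcripts of the genes behind the positive sort markers were found in most cells. Fcgr3, which encodes a CD16 receptor chain, was detected in 91.6% of cells (95% interval 85.5 to 95.7, 120 of 131), Kit, the CD117 receptor, in 81.7% (74.0 to 87.9), Cd34 in 73.3% (64.8 to 80.6) and Fcgr2b, which encodes CD32, in 72.5% (64.04 to 79.95). Kit was found in fewer R2 cells (76.2%, 63.8 to 86.0) than R3 cells (86.8%, 76.4 to 93.8), while the shares with Cd34 were 73.0% and 73.5%. Ly6a, the gene of the Sca-1 protein that the gate excluded, was detected in 80.2% of cells (72.3 to 86.6), with a median of 20.1 TPM in R2 and 49.7 TPM in R3. Ly6a belongs to a family of alike genes, so its level is uncertain. Among the lineage markers, Itgam (CD11b) was detected in 38 of 131 cells (interval 21.4% to 37.6%) and Cd8a in 7 (5.34%), while Cd3e, Cd4 and Cd19 were listed above 1 TPM in 0 of 131 cells (upper limit 2.78%). Of the stained proteins outside the gate, Csf1r (CD115) transcripts were found in 36.6% of cells, Siglec5 in 21.4%, Flt3 (CD135) in 7.63% and Ccr3 in 0 cells (upper limit 2.78%). The share with Kit depended on the threshold: it was 92.4% above 0 TPM and 72.5% above 5 TPM.

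Most genes of primary (azurophilic) granules were expressed in nearly every cell. Mpo (myeloperoxidase), Elane (neutrophil elastase), Prtn3 (proteinase 3) and Ctsg (cathepsin G) were each detected in 131 of 131 cells, with median levels of 22332, 18668, 3897 and 3069 TPM. A few cells were far below these medians yet counted as detected. Before the alike pair was averaged, the lowest levels were 8.17 TPM for Mpo and 7.53 TPM for Elane. Prss57, a serine protease of the same list, was detected in 81.7% of cells (74.6% in R2, 88.2% in R3). The median cell had 8 of the 8 primary granule genes, 8 of the 21 measured granulocytic genes and 4 of the 17 monocytic genes. Of the granulocytic genes, Gstm1 was detected in 97.7% of cells, Anxa1 in 91.6%, Csf3r, the receptor for granulocyte colony-stimulating factor, in 84.0% and Trem3 in 79.4%. Other members included S100a8 (71.0%), Pglyrp1 (69.5%), Fcnb (54.2%), Camp and Lcn2 (17.6% each), Ngp (11.5%) and Ltf, which was found in 0 of 131 cells (upper limit 2.78%), all chosen after their values were seen. Of the monocytic genes, the most often detected were Zeb2 (71.8%), Ms4a6c (69.5%), F13a1 (63.4%) and Irf8 (47.3%). Granulocytic members per cell had a median of 7 in R2 and 10 in R3, and monocytic members 5 and 4.

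Cells with a high granulocytic score had a low monocytic score. Across cells, the rank correlation of the granulocytic score (18 genes) and the monocytic score (14 genes) was -0.348 in R2 (n = 63) and -0.538 in R3 (n = 68), and -0.447 over both sets. Random pairs of matched lists leaned the other way, with 95% of them between 0.0425 and 0.510 in R2 and between -0.0241 and 0.432 in R3. The observed value was below all 10000 random pairs in each set. Because random members were drawn singly, these ranges do not show how often other groups of genes that vary together would be opposed. With the transcription factors left out of both lists the pooled value was -0.275. The axis itself was nearly unrelated to the number of detected genes, with rho 0.0458 in R2 and -0.0989 in R3.

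**Figure D1:**
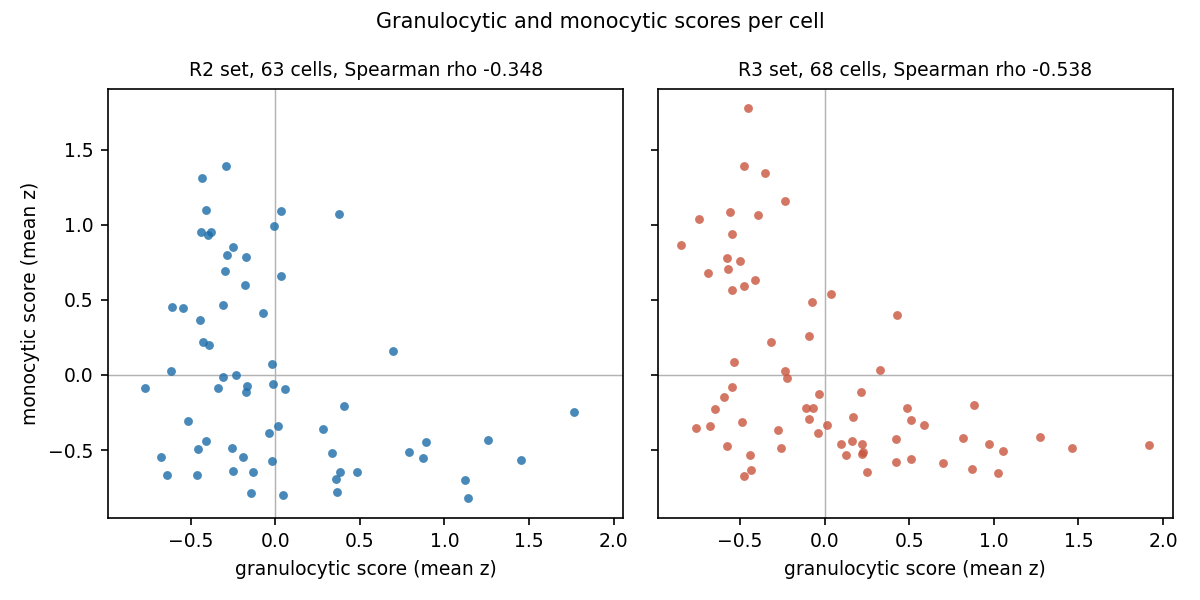
Each point is a cell of the R2 set (left, 63 cells) or the R3 set (right, 68 cells), placed by its granulocytic score (horizontal, mean z) and monocytic score (vertical, mean z). The Spearman rho is -0.348 in R2 and -0.538 in R3.

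Of 9095 genes compared, 79 varied with the granulocytic end in both sets and 70 with the monocytic end. Cd63, a tetraspanin of granule and late endosome membranes, was the gene off every list most closely tied to the granulocytic end (rho 0.812 in R2, 0.852 in R3). It was followed by Srgn, the granule proteoglycan serglycin (0.721 and 0.813), and Serpinb1a, an inhibitor of neutrophil serine proteases (0.673 and 0.692). Other genes at this end were B4galt6, S100a11, Prom1, Actn1 (alpha-actinin), Ncam1, Mcu (the mitochondrial calcium uniporter), Pigr (the polymeric immunoglobulin receptor), Mogat2 and Lta4h, which makes leukotriene B4. Their smaller rho of the sets ran from 0.587 for Lta4h to 0.657 for B4galt6.

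At the monocytic end, Tmsb10, an actin-binding thymosin (rho -0.748 in R2, -0.787 in R3), Pyhin1 (-0.748 and -0.719) and Lgals1, galectin-1 (-0.717 and -0.670), led the genes on no list. Emb, Scpep1, Milr1, Itpripl1, Rasa4, Nrp1 (neuropilin-1), Pld4, S100a10 and the adaptor gene Lat2 followed, down to -0.574 in R2 and -0.592 in R3 for Lat2. Pyhin1 has close relatives in the genome, so its level is uncertain. Cd34, chosen after its values were seen, was also higher at the monocytic end (-0.525 and -0.561), and Kit, likewise chosen after, was not tied to either end (0.131 and 0.110).

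The number of genes passing was far above that of random axes. On no end list, 131 genes passed, against a median of 0 and at most 1 for 200 random axes. Across genes, rho in R2 and rho in R3 correlated at r = 0.478, against at most 0.136 for random axes. Genes are not independent replicates. The members of random axes were drawn singly by mean level. These contrasts therefore do not show how many genes would pass for another group of genes that vary together. Of the 263 genes past the threshold in R2, 96.2% had the same sign in R3. With Pearson correlation in place of ranks, 7 of the 50 named genes no longer passed: Lta4h, Elane, Mpo, Prtn3, Gstm1, Gfi1 and Ctsg.

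**Figure D2:**
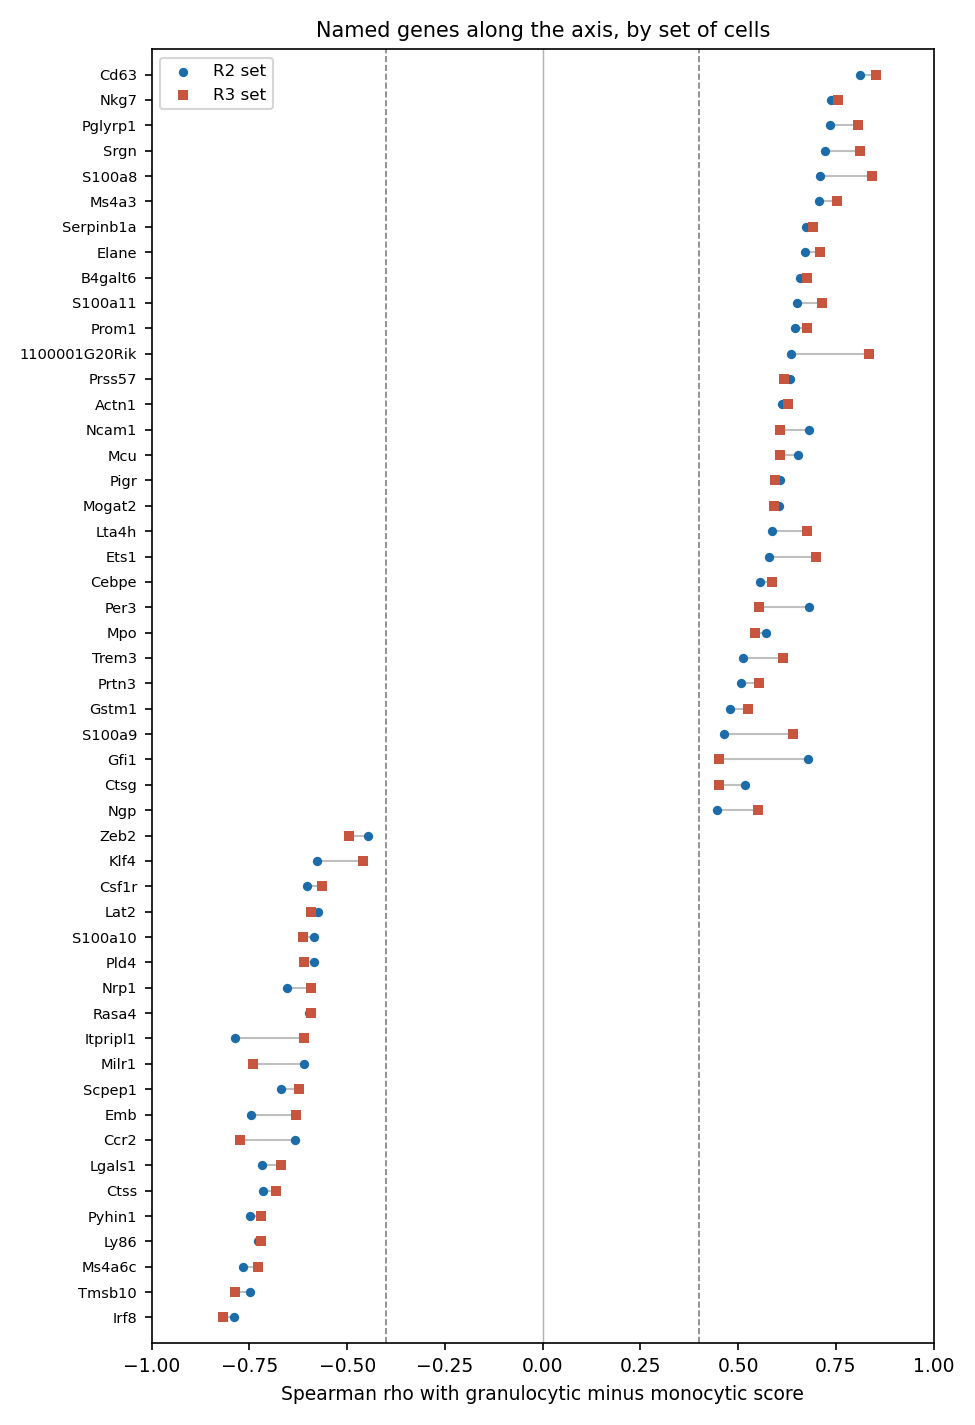
Spearman rho of each of the 50 named genes with the axis (granulocytic minus monocytic score) in the R2 set (circles) and the R3 set (squares), with dashed lines at -0.4 and 0.4. The values of the sets lie on the same side for every gene shown, from Cd63 (0.812 and 0.852) to Irf8 (-0.791 and -0.817).

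Primary granule genes followed the granulocytic end, although they are on neither end list. Of 8 members, 7 passed, with a median rho of 0.605 in R2 and 0.585 in R3, above 100% of random lists. Nkg7 (0.737 and 0.754), Ms4a3 (0.707 and 0.751), Elane (0.670 and 0.7096) and Prss57 (0.633 and 0.617) were the closest, and Mpo, Prtn3 and Ctsg also passed. With Pearson correlation Elane, Mpo, Prtn3 and Ctsg no longer passed. The mean of the set medians of the list was then 0.418, against 0.595 with ranks, and the list still stood apart. The slopes were 0.42 and 0.53 log2 units for Mpo and 1.87 and 1.55 for Nkg7. Of the 18 granulocytic members, 10 passed when each was left out of its own score: S100a8 (0.708 and 0.841, with slopes of 3.95 and 4.55), Pglyrp1, a granule peptidoglycan recognition protein (0.734 and 0.807), 1100001G20Rik, Cebpe, Per3, Trem3, Gstm1, S100a9, Gfi1 and Ngp. Of the 14 monocytic members, 8 passed: Irf8, Ms4a6c (-0.765 and -0.728), Ly86 (-0.729 and -0.721), Ctss, which encodes cathepsin S (-0.714 and -0.681), Ccr2, a chemokine receptor of monocytes (-0.634 and -0.774), Csf1r, Klf4 and Zeb2. The end lists define the axis, so their medians (0.455 and 0.537 for granulocytic, -0.589 and -0.477 for monocytic) are no independent evidence.

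Of 29 transcription factors, 4 passed at the granulocytic end and 3 at the monocytic end. All of these but Ets1 are on the lists that define the axis, so their division between the ends is no independent evidence. Ets1 (0.578 and 0.6999), Cebpe (0.555 and 0.587), the clock gene Per3 (0.682 and 0.554) and Gfi1, a zinc finger repressor needed for neutrophil formation (0.678 and 0.452), were higher at the granulocytic end. Irf8, an interferon regulatory factor needed for monocyte formation (-0.791 and -0.817), Klf4 (-0.577 and -0.459) and Zeb2 (-0.448 and -0.495) were higher at the monocytic end. The remaining 22 did not pass, among them Cebpa (0.0701 and -0.0367), Spi1, which encodes PU.1 (-0.0844 and 0.235), and Runx1 (-0.416 and -0.0606), all 3 chosen after their values were seen.

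Of the other lists, only the macrophage list stood apart in both sets. With Pearson correlation the immediate-early list did so too, at the monocytic end, where the mean of its set medians was -0.135. The median rho of the macrophage list was 0.270 in R2 and 0.250 in R3 over 4 members, at percentiles 100.0 and 99.9 of random lists, and it lay at the granulocytic end because of its passing members, the adhesion molecule gene Vcam1 (0.448 and 0.701) and Slc40a1, the iron exporter ferroportin (0.597 and 0.7102), both chosen after their values were seen. The macrophage median was 0 with all 11 measured members, most of which were rarely detected. Medians that did not stand apart were dendritic (-0.00632 and -0.152), stem and multipotent (0.0643 and -0.114), basophil and mast cell (0.125 and -0.0965), eosinophil (0.176 and 0.166) and B lymphoid (0.117 and -0.0241). The same held for interferon response (0.273 and -0.0533), heat shock (-0.00506 and -0.201), p53 targets (-0.0696 and -0.111), immediate-early genes (-0.119 and -0.0921), ribosomal proteins (-0.0798 and -0.211) and transcription factors (0.0499 and 0.0138). It also held for positive sort genes (0.0312 and 0.164), negative sort genes (0.148 and 0.112), stained proteins outside the gate (-0.0353 and -0.211) and sex-linked genes (-0.0897 and -0.0467). The megakaryocytic, erythroid, T and NK, and stroma and endothelium lists had too few detected members for a median.

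**Figure D3:**
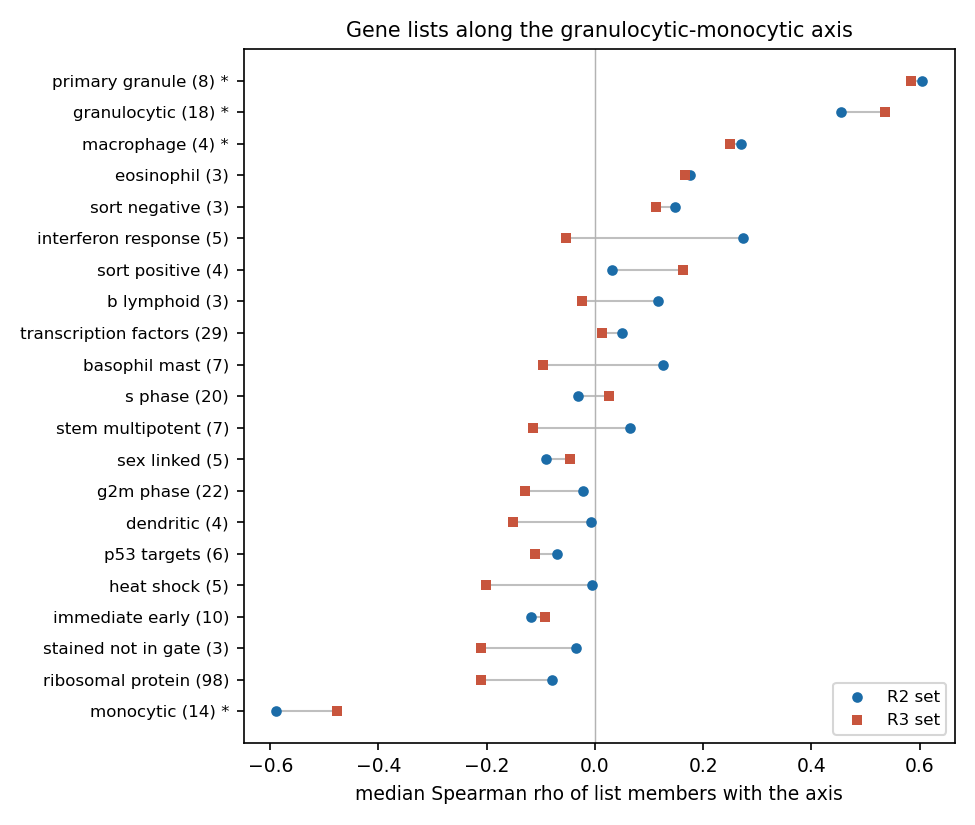
Median Spearman rho of the members of each gene list with the axis in the R2 set (circles) and the R3 set (squares), with the number of members used in parentheses. Asterisks mark the 4 lists beyond the 95% range of random matched lists in both sets; the primary granule list has medians of 0.605 and 0.585.

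Few cells had both Gfi1 and Irf8 transcripts. In R2, 6 of 63 cells had both, 19 had Gfi1 alone, 29 had Irf8 alone and 9 had neither, an odds ratio of 0.0980. In R3 the numbers were 6, 28, 21 and 13 of 68 cells, an odds ratio of 0.133. Over both sets 9.16% of cells had both (95% interval 4.82 to 15.5), 35.9% Gfi1 alone and 38.2% Irf8 alone. The rank correlation of the levels was -0.572 in R2 and -0.408 in R3, below all 10000 random gene pairs of like level in each set. With detection set above 0 TPM, 25.95% of cells had both. The odds ratio over both sets was then 0.138, against 0.112 above 1 TPM.

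Cell cycle scores were within the range of random lists along the axis in both sets. The S phase score had rho -0.0798 in R2 and 0.0694 in R3 with the axis, at percentiles 41.1 and 86.9 of random lists, and the G2/M score -0.0239 and -0.192, at percentiles 47.7 and 20.04. By the median of its members, the G2/M list leaned to the monocytic end in R3 (-0.129, percentile 0.25) but not in R2 (-0.0222, percentile 38.4), and the S phase list to neither (-0.0310 and 0.0254). The S phase and G2/M scores were opposed to each other, with rho -0.249 and -0.353. Among the S phase genes Tyms was detected in 97.7% of cells and Mcm6 in 97.7%, and among the G2/M genes Top2a in 86.3% and Mki67 in 83.2%, so most cells had transcripts of proliferation genes. The S phase score was less tied to the number of detected genes (0.387 and 0.175) than nearly all random lists of like level.

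Some cells carried genes of other fates. At least 3 basophil and mast cell genes were detected in 48.1% of cells (95% interval 39.29 to 56.99, 63 of 131), 33.3% in R2 and 61.8% in R3. This share rested on broadly detected members: Hdc, which makes histamine, was found in 76.3% of all cells and Lmo4 in 68.7%, while Mcpt8, a basophil protease, was found in 40.5% and Cpa3, a mast cell carboxypeptidase, in 21.4%. At least 3 stem and multipotent genes were detected in 17.6% of cells (11.5 to 25.2), mostly Angpt1 (in 19 of these 23 cells), Meis1 (18), Sox4 (15) and Hoxa9 (14). At least 3 dendritic genes were detected in 1 of 63 R2 cells and 9 of 68 R3 cells (7.63% of all cells), led by H2-Ab1 and H2-Aa, which are MHC class II genes of a family of alike sequences, and Tcf4. Where detected, the median was 14.9 TPM for H2-Ab1, 2.825 TPM for H2-Aa and 8.69 TPM for Tcf4. At least 3 members were detected in 4 cells for macrophage, 3 for erythroid, 2 each for megakaryocytic, eosinophil and B lymphoid, and 0 of 131 for T and NK and for stroma and endothelium (upper limit 2.78%). The averaged pair of R2 cells 54 and 56 had 9 of the 11 measured megakaryocytic genes. Its Mpo levels before averaging were 11.08 and 8.17 TPM. This pair stayed among the 131 cells. Single members of the lists of other fates were found in more cells. Cd79b was found in 62.6% of cells, Lepr in 67.2% (median over all cells 1.73 TPM), Slc40a1 in 31.3% and Car2 in 38 of 131 cells. Lck was found in 17.6% and Itga2b in 9.16%. Prg2 was found in 22 of 68 R3 cells but 0 of 63 R2 cells (upper limit 5.69%). Its median where detected was 4.22 TPM, near the threshold. The shares change with the number of members required: 79.4% and 25.95% of cells had at least 2 and at least 4 basophil and mast cell genes, and 36.6% and 9.92% as many stem and multipotent genes.

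Clustering gave 6 clusters. A cluster of 31 cells was monocytic-like by its leading markers, with 17 R2 cells (26.98%, 95% interval 16.6 to 39.7) and 14 R3 cells (20.6%, 11.7 to 32.1). A further 2 clusters, of 24 and 22 cells, were granulocytic-like by their leading markers, with 23 cells (36.5%, 24.7 to 49.6) from R2 and 23 (33.8%, 22.8 to 46.3) from R3. The cluster of 24 cells was mixed, with a mean granulocytic score of 0.41 (standard deviation 0.67). Some of its cells scored below 0, down to -0.547 in R2 and -0.647 in R3. Its median of 4054 detected genes was the lowest of the 6 clusters. The other 54 cells fell in 3 clusters that took no name. The leading genes of these included Serpine2 and Msrb2 in a cluster of 23 cells, Cpa3, Gata2, Egr1 and Angpt1 in one of 19 cells, and the mitosis genes Ube2c, Aurkb and Plk1 in one of 12 cells. These genes define the clusters and are no separate result. Cluster sizes depended on the settings: granulocytic-like cells numbered 23 to 64 and monocytic-like cells 29 to 53 over the alternatives.

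Sex-linked and immediate-early genes were among the genes that differed most between the sets. Xist, the RNA that coats the inactive X chromosome in female cells, had a mean of 0.07 log2 units in R2 and 5.22 in R3, and was detected in 1 of 63 R2 cells and 65 of 68 R3 cells. At least 1 of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was detected in 57 of 63 R2 cells and 0 of 68 R3 cells (upper limit 5.28%); Eif2s3y was the most frequent, in 71.4% of R2 cells. After Xist, the genes with the largest excess in R3 were Erich1 (mean 1.66 in R2, 5.10 in R3), Pigr (2.78 log2 units higher), Gm6402 (detected in 57.1% and 100% of cells) and Isca2 (mean 4.46 and 6.71). The genes with the largest excess in R2 were Zfp36 (R3 minus R2, -4.27), Eif2s3y (-4.18), Ctse, which encodes cathepsin E (-4.12), Fos (-3.79) and Gm15772 (-3.57). Fos and Zfp36 are immediate-early genes, and Fos was detected in 84.1% of R2 cells and 57.4% of R3 cells.

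Over 10275 genes, mean levels of the sets correlated at r = 0.977 across genes. In random subsets of 31 cells the correlation was 0.961 between sets and 0.968 within R2. The median difference, R3 minus R2, was 0.17 log2 units, and 617 genes were at least 1 log2 unit higher in R3 against 110 in R2, sizes with no replicate check because each set is 1 sample. With a pseudocount of 0.1 the median difference was 0.31 and the numbers were 1749 and 308.

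**Figure D4:**
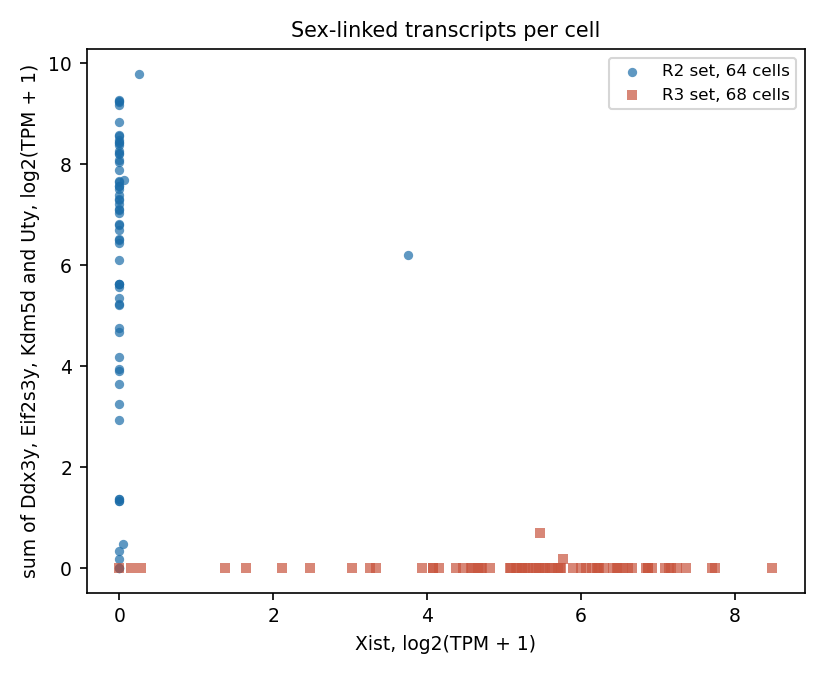
Each point is a cell of the R2 set (circles, 64 cells, the alike pair shown apart) or the R3 set (squares, 68 cells), by Xist (horizontal) and the sum of Ddx3y, Eif2s3y, Kdm5d and Uty (vertical), both as log2(TPM + 1). R3 cells lie along the Xist axis and R2 cells along the Y-linked axis, with 1 R2 cell above 1 TPM on both.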

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

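The counting of the alike pair as 2 cells and the leaving out of the cell with Xist and Y-linked transcripts, or of the 2 cells of each set farthest from the median granulocytic score, were chosen after the data were seen. Of 1086 comparisons of a result with an alternative, 1027 kept their call or stayed within the allowed range. Some of these comparisons could hardly fail, so the count overstates how stable the results are. With rho of 0.5 all 50 named genes were counted as kept. Yet the smaller rho of the sets was below 0.5 for Gfi1 (0.452), Ctsg (0.451) and Ngp (0.446), among others. The named genes tested in R2 alone or R3 alone had already been chosen for passing in both sets. The granulocytic and monocytic scores stayed opposed under every alternative run, with pooled rho from -0.275 (transcription factors left out of both lists) to -0.533 (adjusted for genes detected). Given the primary granule score, the mean over the sets of rho with the axis was -0.147 for S phase and -0.220 for G2/M. Neither list stood apart in both sets from random lists adjusted alike. With R2 alone, 120 genes passed at the granulocytic end and 144 at the monocytic end, and with R3 alone 144 and 143, because agreement of the sets was no longer required. With rho of 0.5, 37 passed at each end, which are by definition among the main genes. The macrophage median was 0 with every measured member, of which 4 were found in no cell and 3 in fewer than 5%.

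At other detection thresholds shares moved by construction. Above 0 TPM, Kit was found in 92.4% of cells, Cd34 in 86.3%, Itgam in 41.2%, 3 stem and multipotent genes in 29.01%, 3 basophil and mast cell genes in 70.2%, and both Gfi1 and Irf8 in 25.95%, with an odds ratio of 0.138 for Gfi1 and Irf8. Above 5 TPM, Kit was found in 72.5%, 3 stem and multipotent genes in 10.7% and 3 basophil and mast cell genes in 33.6%, and the odds ratio of Gfi1 and Irf8 was 0.170. With at least 2 or at least 4 members, stem and multipotent genes were found in 36.6% or 9.92% of cells and basophil and mast cell genes in 79.4% or 25.95%. Granulocytic-like cells numbered 23 with fewer variable genes, 26 without cell cycle genes and 26 with Ward clustering, which gave 53 monocytic-like cells; the cause was not tested. With a pseudocount of 0.1, 1749 genes were at least 1 log2 unit higher in R3 and 308 in R2, because a smaller pseudocount widens differences of low genes. Unknown depth limits all statements on genes that were not detected.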

Other observations

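The tests of the shift between sets and of both sex-linked explanations, and the score pairs, the genes tied to other scores, the lists compared between sets and the Ly6a values, were chosen after the results were seen.

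Cells with stem and multipotent transcripts were low in granulocytic ones. The stem and multipotent score (7 genes) had rho -0.366 with the granulocytic score in R2 and -0.579 in R3, beyond 95% of random lists in both, and -0.153 and 0.108 with the monocytic score, within that range. Over both sets 7 genes passed with this score and 10 against it. Gpr56, an adhesion receptor (0.559 in R2, 0.494 in R3), Tmem176b (0.469 and 0.479) and the mast cell gene Cpa3 (0.437 and 0.426) went with it. Fcnb, a ficolin of neutrophil granules (-0.637 and -0.584), Ly6c2 (-0.538 and -0.647), the lectin receptor Clec5a (-0.510 and -0.570) and Cebpb (-0.426 and -0.409) went against it. The basophil and mast cell score was opposed to the monocytic score instead (-0.522 in R2 and -0.255 in R3, where the random range ended close by at -0.244), with Myb (0.486 and 0.427) going with it and the signalling adaptor Tyrobp (-0.556 and -0.489) against it. The immediate-early score was opposed to the primary granule score (-0.434 and -0.305, at percentiles 0.01 and 0.63).

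Some lists also differed between the sets. All 18 granulocytic genes were higher in R3, by a median of 0.63 log2 units, and 13 of 14 monocytic genes were higher in R2 (median of R3 minus R2, -0.46). All 10 immediate-early genes were higher in R2 (-1.94), among them Egr1 (-2.78), Dusp1 (-2.71), Ier2 (-2.08) and Jun (-1.79). Further lists beyond 95% of random lists of like level were primary granule (0.33), G2/M (-0.10, 13 of 22 higher in R2), p53 targets (-0.29, 3 of 6), ribosomal protein (-0.07, 62 of 98), sex-linked (-1.24) and macrophage genes (0.57). All but the macrophage list stayed beyond that range with a pseudocount of 0.1 and after scaling each cell to the mean cell. R2 cells also had fewer detected genes, so a difference in cell quality or handling was not excluded. Each set is 1 sample, so these are differences between these collections of cells.

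Ly6a went with its relatives Ly6c1 (rho 0.776 in R2, 0.817 in R3) and Ly6c2 (0.735 and 0.871), but not with Ly6e (-0.0184 and 0.0363), and was lower where the stem and multipotent score was high (-0.559 and -0.555). The cell that had both Xist (12.4 TPM) and Y-linked transcripts (72.8 TPM in sum) had 4532 detected genes. The alike R2 cells 54 and 56 shared 91.9% of their detected genes, against at most 59.3% for any other pair.

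The opposition of the granulocytic and monocytic scores was weighed against technical explanations. Adjusted for the number of genes detected per cell the pooled rho was -0.533, and after rescaling without ribosomal protein genes and the 50 most abundant genes it was -0.433, both below the range of 95% of random list pairs treated alike (-0.163 to 0.203, and 0.0517 to 0.409). These ranges come from genes drawn singly and are no yardstick for other groups of genes that vary together. A shift between the sets cannot set cells of the same set apart, and inside R2, the set with the weaker value, rho was -0.348 (random range 0.0425 to 0.510). One hypothesis is that the cells differ in how far they lean to the granulocytic or monocytic fate; this may hold for part of them only. The design has no group that tests it.

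The low granulocytic score of cells with stem and multipotent genes was weighed in the same way. Adjusted for genes detected, rho was -0.3998 in R2, the set nearer to its random range (-0.325 to 0.234), and adjusted for the immediate-early score, taken as a sign of handling, it was -0.304 in R2 (random range -0.211 to 0.315). Neither adjustment brought rho inside its range, although the R2 values lie close to the ranges. Both measures are imperfect stand-ins for depth and handling, so an adjustment may remove only part of an effect. Neither explanation is therefore excluded. A hypothesis left open is that these cells may be earlier progenitors inside the gate. No biological explanation was tested, because the labels give no stage.

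For the division of Xist and Y-linked transcripts, the hypothesis that each set held cells of both sexes needs R3 cells with Y-linked transcripts. In R3, 0 of 68 cells had them and 65 had Xist, which argues against it for R3. In R2, 57 of 63 cells had a Y-linked gene and 1 had Xist. By these transcripts most R2 cells read as male and most R3 cells as female. The hypothesis that the sets came from animals of different sex rests on this reading alone, with no separate check. R2 cells with Xist plus R3 cells with a Y-linked gene came to 1, which restates the division and adds no support. The labels give no sex, and sex, handling day and set cannot be separated here, so the other differences between R2 and R3 stay open as to their source.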
